A study of Mus musculus with 10 samples.

How the data were processed

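RNA was sequenced from lung tumors and liver metastases of RPR2 mice and of RPR2;Nfibf/f mice, called Nfib-floxed here. Per the labels' protocols, tumors were macrodissected at morbidity and snap-frozen, polyA RNA was selected from total RNA, and libraries were made with a NEBNext Ultra II kit. Whether strand was kept is not given in the sources used here, so a gene and an antisense partner cannot be told apart. Per the submitters' processing notes, bcl2fastq 2.20, Salmon 0.12.0 and R 4.1.0 were used with genome build GRCm38. The annotation version and settings are not given in the sources used here. The table the authors deposited holds TPM per gene, and each library sums to 1000000. TPM keeps no depth, so the depth per library is unknown and no counting interval or detection floor is given. Salmon estimates how reads are shared among similar transcripts, so levels of genes with near-identical copies are uncertain.

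The 10 libraries were assigned to 4 groups and 6 mice by their labels. Of the 35288 gene identifiers in the table, 35028 were found in the GENCODE annotation of GRCm38 used for positions, 34728 with the same symbol, and 260 were not found. No library pair held identical values. Pearson correlations of log2(TPM + 1) were 0.84 to 0.949 within groups and 0.742 to 0.932 between groups. The highest between groups was that of the Nfib-floxed metastasis of JHK1398 with the RPR2 lung tumor of JHK1373. It lay above the metastasis's 0.916 with the other Nfib-floxed metastasis and its 0.809 with the lung tumor of JHK1398. That lung tumor correlated at 0.7417 to 0.8865 with the other libraries, so the 0.809 says little about the metastasis.

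Differences were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), for 15503 genes with a mean of at least 1 TPM over the 10 libraries. A single model of the 4 groups gave 7 comparisons: the Nfib genotype in lung tumors and in liver metastases, metastases against lung tumors in each genotype, the interaction, and the mean genotype and mean tissue effects. The residual degrees of freedom were 6 and the prior 4.56. Tests were two-sided with moderated variances and a mean trend, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. For the mean genotype effect, mouse was a random effect (estimated correlation 0.051). Nfib was also compared between lung tumors by an exact permutation test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.

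The 47 gene lists were 22 of tumor programs, 22 of other cell types that lung, liver or a tumor can hold and 3 of RNA quality, sex or stress. They named 798 symbols, of which 12 were not matched. Each was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance, were alternatives. The estimated correlation and fry were computed without the mouse effect.

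Named genes follow a rule. Per comparison it takes the 12 largest rises and the 12 largest falls among genes past the threshold with a mean of at least 5 TPM in the higher group. In comparisons of groups, the values of both groups must also not overlap. Where fewer than 5 pass, it takes the 5 with the smallest raw p in each direction. It adds the NFI family, Rb1, Trp53, Rbl2, regulators including Yap1, Myc, Mycl and Mycn, and up to 4 members of each list called (2 where none passed). Predicted genes and antigen receptor segments were passed over, and some genes that the rule takes are not reported here. The groups, the tests of the comparisons, the lists, this rule and the alternatives were fixed before the data were examined, except for 1 alternative added later, which leaves out the lung tumors of JHK1394 and JHK1398. Explanations were tested later, and the closing section names the tests chosen after the result was seen.

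The alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM, quantile normalization, median centring, and rescaling without the genes of the cell type lists. Further ones were robust moderation, array weights, a minimum log2 change of 1, mouse as a random or fixed block, fits of the 2 compared groups alone, and leaving out each library in turn. The labels give lung tumors and metastases of 4 mice the same mouse tag, so these samples are pairs by design. Their deviations from the group means correlated at -0.02, -0.01, 0.04 and 0.05 across genes.

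The tests were themselves tested on simulated data with 200 changed genes among 15503 for each comparison. Recovery was scored over the raised genes and over those lowered genes whose mean log2(TPM + 1) was at least the shift. Lowered genes at lower levels were left out, so recovery over all changed genes may be lower than the percentages given. False calls numbered 1 to 7 per comparison. With no gene changed, 1 gene was called in the lung comparison, 2 in the mean tissue effect and none in the others, and no list was called. When the epithelial list was shifted by 1 log2 unit in the simulated liver comparison, camera gave an adjusted p of 3.59e-17, the estimated correlation 0.00285 and fry 0.00012. The simulated noise was drawn for each gene on its own, so the members of a list were not correlated. In the data the estimated correlation was 0.41 for epithelial, 0.51 for cell cycle and 0.67 for hepatocyte genes. The simulation therefore cannot show how often camera at the preset correlation falsely calls a list in the data. Xist was not analysed here.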

Results

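Gene expression was measured by RNA sequencing in tumors of a mouse model of small cell lung cancer, a neuroendocrine tumor that spreads early. In the model named RPR2, the tumor suppressor genes Rb1, Trp53 and Rbl2 are deleted in the lung. In the second genotype, RPR2;Nfibf/f, the tumors carry in addition conditional (floxed) alleles of Nfib, which encodes a transcription factor of the nuclear factor I family. This genotype is called Nfib-floxed here. The 10 libraries came from 6 mice, 3 of each genotype. They fall into 4 groups: RPR2 lung tumors (n = 3), Nfib-floxed lung tumors (n = 3), RPR2 liver metastases (n = 2) and Nfib-floxed liver metastases (n = 2). The liver metastases came from 4 of the mice that also gave a lung tumor. Levels are given in TPM, transcripts normalized for gene length and library total, and the 15503 genes with a mean of at least 1 TPM were tested. Each library sums to 1000000 TPM, so the table keeps no sequencing depth and the depth behind each value is unknown. Values are mean ± SD of TPM over the libraries of a group, and changes are differences of mean log2(TPM + 1) ± standard error from limma. On this scale the change of a gene with a low level is understated. The limma p-values rest on a spread per gene that was pooled over the 4 groups and comes mostly from the lung tumors. Except in the mean genotype effect, the lung tumor and the metastasis of a mouse were treated as independent. Positions are those of mouse genome build GRCm38.

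Nfib itself (ENSMUSG00000008575, chromosome 4, 82290173 to 82705750, minus strand) was measured first. Its level in RPR2 lung tumors was 77.1 ± 45.3 TPM, with 85.3, 28.3 and 118 TPM in the tumors of JHK1373, JHK1394 and JHK1548. In Nfib-floxed lung tumors it was 34.4 ± 6.85 TPM, with 38.0, 26.5 and 38.6 TPM in those of JHK1398, JHK1399 and JHK997. The difference of -42.7 TPM gave p = 0.3 in a two-sided exact permutation test (n = 3 and 3), where 20 arrangements allow no p below 0.1. The RPR2 metastases had 62.8 TPM (JHK1373) and 643 TPM (JHK1394), and the Nfib-floxed metastases 46.1 TPM (JHK1398) and 41.3 TPM (JHK1399). The labels used here do not say which part of Nfib is floxed, and a value for the whole gene need not show the loss of a part of it, so these levels check the genotype labels little. Among the other family members, Nfix stood at 107 ± 92.6 TPM in RPR2 metastases and 11.2 ± 12.9 TPM in Nfib-floxed metastases, a difference that missed the threshold (log2 change -3.39 ± 1.04, adjusted p = 0.145). In RPR2 lung tumors, the genes deleted in the model had whole-gene levels of 117 ± 25.7 TPM for Rb1, 15.7 ± 0.96 TPM for Trp53 and 19.6 ± 8.08 TPM for Rbl2. No member of the NFI family, none of these 3 genes and none of Yap1, Myc, Mycl and Mycn passed the threshold in any of the 7 comparisons.

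**Figure D1:**
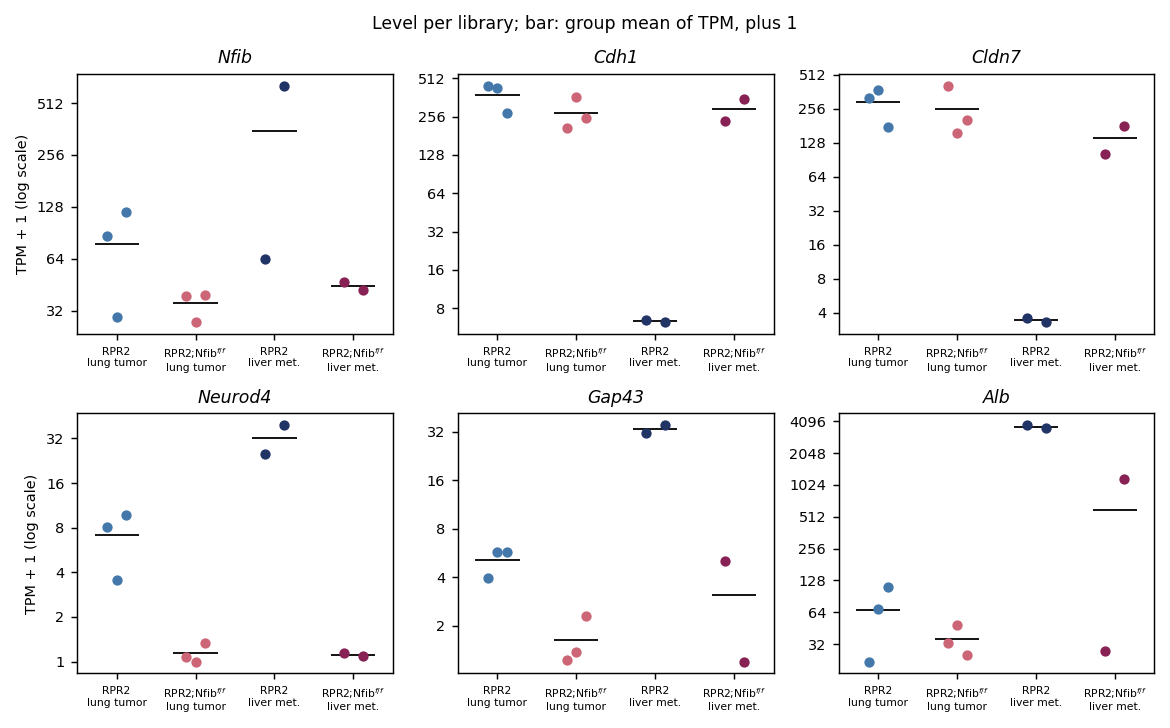
TPM plus 1 of 6 genes in each of the 10 libraries, on a log axis. Each point is 1 library, the columns are the 4 groups, and the bar is the group mean of TPM plus 1. Cdh1 and Cldn7 lie under 6 TPM in both RPR2 metastases and above 100 TPM in both Nfib-floxed metastases, while Neurod4 and Gap43 show the opposite order.

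The first comparison asked how the Nfib genotype affects the primary tumor in the lung. No gene passed the threshold between Nfib-floxed and RPR2 lung tumors. Among the genes with the smallest raw p was Neurod4, a neurogenic transcription factor, at 6.09 ± 3.2 TPM in RPR2 and 0.134 ± 0.17 TPM in Nfib-floxed lung tumors (log2 change -2.53 ± 0.46, adjusted p = 0.595). Lmnb1, which encodes lamin B1, stood at 115 ± 33.7 against 39.6 ± 6.12 TPM, and Rasgrf1, a guanine nucleotide exchange factor, at 5.58 ± 2.34 against 61.6 ± 39.1 TPM, all without passing. Mycl, a MYC family gene, had 132 ± 23.1 TPM in RPR2 and 27.1 ± 19.2 TPM in Nfib-floxed lung tumors (log2 change -2.45 ± 1.0, adjusted p = 0.606).

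Also among the genes with the smallest raw p in the lung comparison were Cd59a (log2 change 2.41), Klk1b22 (4.04), Med12 (1.81) and Rps4l (2.62). In the other direction lay Naf1 (-1.49), Cyp39a1 (-1.54) and Serpinb12 (-2.87). Of the 47 gene lists, camera called 7 in lung tumors. The list of cell cycle genes lay lower in Nfib-floxed tumors, with a median log2 difference of -0.80 and 35 of 36 members below 0. Interferon response genes had a median of -0.99, with 28 of 29 members below 0, and epithelial genes a median of -0.39. No member of these lists passed over all genes or when adjusted over the list alone. Higher lists were mitochondrially encoded genes (0.69), endothelium (0.42) and fibroblast stroma (0.34), and Kupffer cell markers lay lower (-0.63, 1 member down when adjusted over the list alone). With an estimated correlation none of the 7 lists was called (adjusted p = 0.996 for each). Beside these lists, the lung tumor of JHK1398 held 12.9% mitochondrially encoded transcripts against 4.32% to 7.13% in the other lung tumors, and Scgb1a1, a club cell secretory protein, made up 5.02% of its TPM. Scgb1a1 also made up 5.48% in the RPR2 lung tumor of JHK1394 and 0.136% to 0.965% in the others.

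By limma, 1230 genes had an unadjusted p under 0.05 in lung tumors, 488 of them higher in Nfib-floxed tumors, and the smallest adjusted p was 0.272. The groups did not overlap at 14.5% of genes, against 10% by chance. The count was 1 without the RPR2 lung tumor of JHK1373 and 1 with a pseudocount of 0.1. In simulated data for this comparison the test recovered 1.54%, 42.9% and 87% of genes changed by 1, 2 and 4 log2 units.

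The comparison of liver metastases asked how the Nfib genotype affects tumors that have spread. Epithelial genes were higher in Nfib-floxed than in RPR2 metastases. Cdh1 (ENSMUSG00000000303, chromosome 8, 106603351 to 106670246), which encodes the adhesion protein E-cadherin, had 5.33 ± 0.182 TPM in RPR2 metastases and 294 ± 81.9 TPM in Nfib-floxed metastases (n = 2 each, log2 change 5.51 ± 0.37, adjusted p = 0.000125). The tight junction gene Cldn7 (2.46 ± 0.221 against 139 ± 54.2 TPM) and the epithelial splicing regulator Esrp1 (1.64 ± 0.0612 against 114 ± 55.7 TPM) rose likewise. In the other direction, Neurod4 fell from 31.3 ± 9.99 to 0.114 ± 0.0281 TPM (log2 change -4.82 ± 0.56, adjusted p = 0.00222), and Grik2, a glutamate receptor subunit, from 26.7 ± 3.86 to 0.0597 ± 0.00981 TPM.

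Of the 26 measured genes in the epithelial list, 18 rose in Nfib-floxed against RPR2 metastases, none fell and 8 did not pass. Adjusted over the list alone, 23 rose. The list's median log2 change was 2.73 (camera adjusted p = 2.21e-37), with adjusted p = 0.188 with an estimated correlation and 0.00384 in fry. Spint1, a protease inhibitor of epithelia, rose by 5.04 ± 0.59 log2 units. Outside the list, the kinase genes Ret (4.77 ± 0.33) and Mapk13 (5.63 ± 0.56), R3hdml (6.04 ± 0.36), Ano9 (5.59), Aldh1a3 (5.20), Ap1m2 (4.77), the mechanosensitive channel gene Piezo2 (5.19) and the endothelial marker Vwf (5.08) rose too. Of the 37 genes of axon growth and neuronal migration, 5 fell, among them Dcx (-3.85 ± 0.73), Gap43 (-3.76 ± 0.66), Epha5 (-3.5 ± 0.50) and Slit2 (-2.46 ± 0.49), and none rose. Adjusted over the list alone, 7 fell and 3 rose (median -0.81, adjusted p = 0.369 with an estimated correlation). Among the other falls were those of Thbs4 (-5.73), Cacng7 (-5.62), Mpdz (-5.46, on chromosome 4 near Nfib), Slc6a15 (-5.14), Gng4 (-5.00), Thrsp (-4.87), Lingo1 (-4.86), Tub (-4.74), Adamts10 (-4.62) and Hoxb8 (-4.47).

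Genes of hypoxia and glycolysis were higher in Nfib-floxed metastases. Of 21 members 4 rose, namely Ankrd37 (3.10 ± 0.37), the glycolytic enzyme gene Aldoa (2.17 ± 0.36), Vegfa (2.13 ± 0.43) and P4ha1 (1.93 ± 0.38), none fell, and 8 rose when adjusted over the list alone (adjusted p = 0.369 with an estimated correlation). Antigen presentation genes had a median of 1.23 with no member past the threshold and 5 up when adjusted over the list alone (adjusted p = 0.886 with an estimated correlation). Beside these groups, markers of liver cells were lower in Nfib-floxed metastases. Of 34 hepatocyte genes 3 fell, including Cyp2e1 (-4.09 ± 0.90), and 30 fell when adjusted over the list alone (median -3.69, adjusted p = 0.375 with an estimated correlation). Albumin (Alb) stood at 3658 ± 145 TPM in RPR2 metastases, and at 26.3 TPM (JHK1398) and 1159 TPM (JHK1399) in Nfib-floxed ones. Of 8 Kupffer cell genes 3 fell (Marco, Clec4f and Vsig4), and 7 when adjusted over the list alone (median -2.26, adjusted p = 0.188 with an estimated correlation). The remaining lists called by camera were lower: neutrophil (-1.27), macrophage and monocyte (-0.74), B and plasma cell (-1.47) and cell cycle genes (-0.28), with no member past the threshold and adjusted p from 0.843 to 0.887 with an estimated correlation.

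In all, 316 genes differed between genotypes in liver metastases, 175 higher and 141 lower in Nfib-floxed ones. Whether the metastasis of JHK1398 has the right label was not settled, for reasons given in the closing section. The groups did not overlap at 45.8% of genes, against 33.3% by chance for 2 against 2. The count was 175 without the RPR2 metastasis of JHK1373, 110 without that of JHK1394 and 143 without the Nfib-floxed metastasis of JHK1398, with the lone sample of a group assumed to vary like the others. It was 193 for genes with a mean of at least 5 TPM, and 0 when the 4 metastases were fitted alone. In simulated data for this comparison the test recovered 0%, 16.4% and 87% of genes changed by 1, 2 and 4 log2 units.

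Metastases were next compared with lung tumors within RPR2 mice. Epithelial genes fell in the metastases: Cdh1 from 381 ± 96.4 TPM in lung tumors (n = 3) to 5.33 ± 0.182 TPM in metastases (n = 2, log2 change -5.88 ± 0.34, adjusted p = 3.14e-05), Cldn7 (-6.33 ± 0.46), Muc1 (-5.69 ± 0.69) and Spint1 (-5.56 ± 0.54). Of the 26 epithelial genes 23 fell and none rose, and all 26 fell when adjusted over the list alone (median -4.04, adjusted p = 0.246 with an estimated correlation and 0.00069 in fry). In the other direction, the growth cone gene Gap43 rose from 4.14 ± 1.01 to 32.2 ± 2.64 TPM and Epha5, an ephrin receptor, from 0.613 ± 0.456 to 13.5 ± 3.03 TPM. Of the 37 axon growth and neuronal migration genes, 5 rose and 2 fell (8 and 4 when adjusted over the list alone, adjusted p = 0.512 with an estimated correlation), with Dcx up by 3.49 ± 0.66 and Nrcam down (-2.02 ± 0.49).

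Beside these changes, markers of normal lung and liver parted the RPR2 groups. The secretory genes Scgb1a1 (-8.38 ± 1.51), Scgb3a2 (-8.28) and Scgb3a1 (-7.29), Cbr2 (-6.79) and surfactant gene Sftpb (-6.55) fell in metastases. Of 8 club cell genes 4 fell (7 adjusted over the list alone, adjusted p = 0.325 with an estimated correlation), and of 11 alveolar type 2 genes 2 fell (9 adjusted over the list alone, adjusted p = 0.559 with an estimated correlation). Hepatocyte genes rose, 27 of 34 (30 adjusted over the list alone, adjusted p = 0.325 with an estimated correlation), with Apoa4 up by 7.0 ± 1.01 and Alb by 6.05 ± 1.21. Gc (6.48), Ahsg (6.14), Apoa1 (6.04), Fabp1 (5.95), Apoa2 (5.82), Hpx (5.78), Serpina1c (5.57), Hsd17b13 (5.56) and Serpina3k (5.56) rose with them. Serpina1 and Serpina3 genes belong to families of near-identical copies, so the level of a single member is uncertain. Kupffer cell genes Clec4f, Cd5l and Vsig4 rose (3 of 8, also 3 adjusted over the list alone, adjusted p = 0.325 with an estimated correlation).

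Immune signalling genes were lower in RPR2 metastases, but the levels of some were uneven among lung tumors. In the lung tumor of JHK1394, a run of 11 neighboring genes with Ifit1, Ifit2 and Ifit3 had a median log2 difference of 1.725 to the other libraries. The highest of 100 shuffles of gene order was 1.801. How much of the falls below comes from the share of normal lung in that tumor was not settled. Of 29 interferon response genes 9 fell, among them Oasl2 (-3.85 ± 0.75) and Ifit1 (-3.61 ± 0.61), and 25 when adjusted over the list alone (adjusted p = 0.512 with an estimated correlation and 0.0377 in fry). Of 20 antigen presentation genes 10 fell, including the immunoproteasome gene Psmb9 (-2.71 ± 0.67) and B2m (-2.34 ± 0.53), and 13 when adjusted over the list alone (adjusted p = 0.512 with an estimated correlation). By list median, lung tumors also held higher macrophage and monocyte markers (median -1.04, 1 of 19 fell) and B and plasma cell markers (-1.43, none of 9). The same held for alveolar type 1 cell (-2.62, 3 of 10 fell), lung endothelium (-1.91, 2 of 9 fell) and mesothelium markers (-1.58, none of 5). The macrophage and monocyte list summed to 8265 TPM in the lung tumor of JHK1394 but to 1231 and 2284 TPM in those of JHK1373 and JHK1548. In the metastases of JHK1373 and JHK1394 it summed to 3236 and 2803 TPM, so by sum it was not higher in every lung tumor. Non-neuroendocrine genes (4 of 26 fell), integrin and adhesion genes (3 of 22 fell and 1 rose), NF-kB inflammation genes (none of 20) and hypoxia genes (2 of 21 fell, Ankrd37 and Aldoa) lay lower too. Cell cycle genes (median 0.51, 1 of 36 rose, Birc5), ribosome biogenesis genes (0.44, 1 of 26 rose, Gnl3) and erythroid genes (1.64, none of 6) lay higher. The erythroid list summed to 64959 TPM in the metastasis of JHK1373. In that of JHK1394 it summed to 4142 TPM, within the range of the RPR2 lung tumors (3515 to 6490 TPM). Over these lists the adjusted p ranged from 0.512 to 0.634 with an estimated correlation. The other large falls in RPR2 metastases were those of Tspan1 (-6.13), Sprr1a (-5.74), R3hdml (-5.74), Mapk13 (-5.74) and Ano9 (-5.69). Nfib did not pass the threshold (log2 change 1.60 ± 0.83, and -0.069 without the metastasis of JHK1394).

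The comparison of metastasis against lung tumor in RPR2 mice gave 869 changed genes, 316 higher and 553 lower in metastases. With quantile normalization the split was 407 higher and 408 lower and with median centring 394 and 382, and the median log2 change of all genes was -0.154. With mouse as a fixed block the count was 530, with array weights 2069. It was 567 and 516 without the RPR2 lung tumors of JHK1373 and JHK1394, and 317 and 243 without the metastases of JHK1373 and JHK1394. Groups did not overlap at 46.1% of genes, against 20% by chance, and in simulated data 1.52%, 24.2% and 84.9% of genes changed by 1, 2 and 4 log2 units were recovered.

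In Nfib-floxed mice, few genes parted metastases from lung tumors, and those that passed were lower in the metastases. They included Cbr2, a club cell enzyme (444 ± 500.5 to 0.727 ± 0.0821 TPM, log2 change -7.40 ± 0.92, adjusted p = 0.0193), Jchain, the joining chain of secreted antibodies (-6.65 ± 0.87), and Mgp, a matrix protein gene (905 ± 518 to 29.8 ± 3.6 TPM). Fmo2 (-4.88), Rasgrf1 (-4.69), Rps4l (-4.29), Samd9l (-4.08) and Mfap5 (-3.57) fell too, and Rps4l shares sequence with other ribosomal protein genes, so its level is uncertain. No epithelial gene passed in this comparison (median -0.20), and Cdh1 stood at 275 ± 81.5 TPM in lung tumors and 294 ± 81.9 TPM in metastases.

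Markers of normal lung, immune and vascular cells lay lower in the Nfib-floxed metastases. Of 8 club cell genes 1 fell (5 adjusted over the list alone, adjusted p = 0.365 with an estimated correlation), and of 9 B and plasma cell genes 2 fell (8 adjusted over the list alone, adjusted p = 0.365 with an estimated correlation). No member passed in the lists of macrophages and monocytes (median -1.57), alveolar macrophages (-1.52), alveolar type 2 cells (-3.03), endothelium (-1.05), lung endothelium (-1.76) and fibroblast stroma (-0.65). The same held for mesenchymal (-0.52), non-neuroendocrine (-1.43), interferon response (-1.31), antigen presentation (-0.82), NF-kB (-0.89) and integrin and adhesion genes (-0.65). Adjusted over the list alone, 4 macrophage, 1 alveolar macrophage, 4 alveolar type 2, 5 endothelium, 4 lung endothelium and 4 fibroblast genes fell. So did 4 antigen presentation and 2 integrin and adhesion genes. Higher in metastases, again with no member past the threshold, were hepatocyte (1.47), cell cycle (1.44, 21 of 36 up when adjusted over the list alone), ribosome biogenesis (0.43), hypoxia (0.48) and oxidative phosphorylation genes (0.21). The hepatocyte list summed to 4674 TPM in the metastasis of JHK1399 but to 620 TPM in that of JHK1398, below the 1560 TPM of its lung tumor. Over these lists the adjusted p ranged from 0.365 to 0.687 with an estimated correlation. In all 19 genes fell and none rose, and 1455 genes had an unadjusted p under 0.05. The count was 0 without the lung tumor of JHK1398, 29 without that of JHK1399 and 4 without that of JHK997, 9 (8 up and 1 down) without the metastasis of JHK1398 and 5 (3 up and 2 down) without that of JHK1399. Without the lung tumors of JHK1394 and JHK1398, which had the highest shares of Scgb1a1 and were left out after this was seen, it was 1. It was 40 with a pseudocount of 0.1, 1 with a pseudocount of 5, 2 without the filter, 9 with median centring, and 0 with these 2 groups fitted alone. Groups did not overlap at 22.5% of genes, against 20% by chance, and in simulated data 3.03%, 45.8% and 83.3% of genes changed by 1, 2 and 4 log2 units were recovered.

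Whether the genotype effect differed between tissues was tested as an interaction. Epithelial genes differed: the genotype effect on Cdh1 was -0.48 log2 units in lung tumors and 5.51 in metastases, a difference of 5.99 ± 0.48 (adjusted p = 0.000666). Of the 26 epithelial genes 14 passed, all with a higher effect in metastases, and 25 did when adjusted over the list alone (median 3.5, adjusted p = 0.189 with an estimated correlation and 0.00785 in fry). The 14 became 7 and 9 without the RPR2 lung tumors of JHK1373 and JHK1394, 7 and 8 without the RPR2 metastases of JHK1373 and JHK1394, 6 without the lung tumors of JHK1394 and JHK1398, and 3 with mouse as a fixed block. Tspan1 (6.40 ± 0.74), Esrp1 (5.68 ± 0.66) and Ret (5.6 ± 0.42) were among the genes with a higher genotype effect in metastases. The genotype effect was lower in metastases for Grik2 (-4.51 ± 0.57), Slc6a15 (-4.19 ± 0.66), Epha5 (-3.45 ± 0.64) and Adamts10 (-5.31 ± 0.77). Beside them, hepatocyte genes lay lower (median -3.02, none of 34 passed, adjusted p = 0.575 with an estimated correlation). The median difference of all genes was 0.11. Camera called 13 lists in all, at an adjusted p from 0.189 to 0.912 with an estimated correlation.

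In all, 90 genes passed the interaction test, 76 with a higher and 14 with a lower genotype effect in metastases than in lung tumors. This test shares the RPR2 metastases with the comparisons of genotypes in the liver and of tissues in RPR2 mice, so the 3 are not independent. With mouse as a fixed block the count was 13, and with array weights the count was 142. Without the RPR2 lung tumors of JHK1373, JHK1394 and JHK1548 it was 25, 32 and 40, and without the Nfib-floxed lung tumor of JHK1399 it was 46. Without the RPR2 metastases of JHK1373 and JHK1394 it was 24 and 26, and without the Nfib-floxed metastasis of JHK1398 it was 40. The count was 24 without the lung tumors of JHK1394 and JHK1398. In simulated data for this test 0%, 1.67% and 46.2% of genes changed by 1, 2 and 4 log2 units were recovered.

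**Figure D2:**
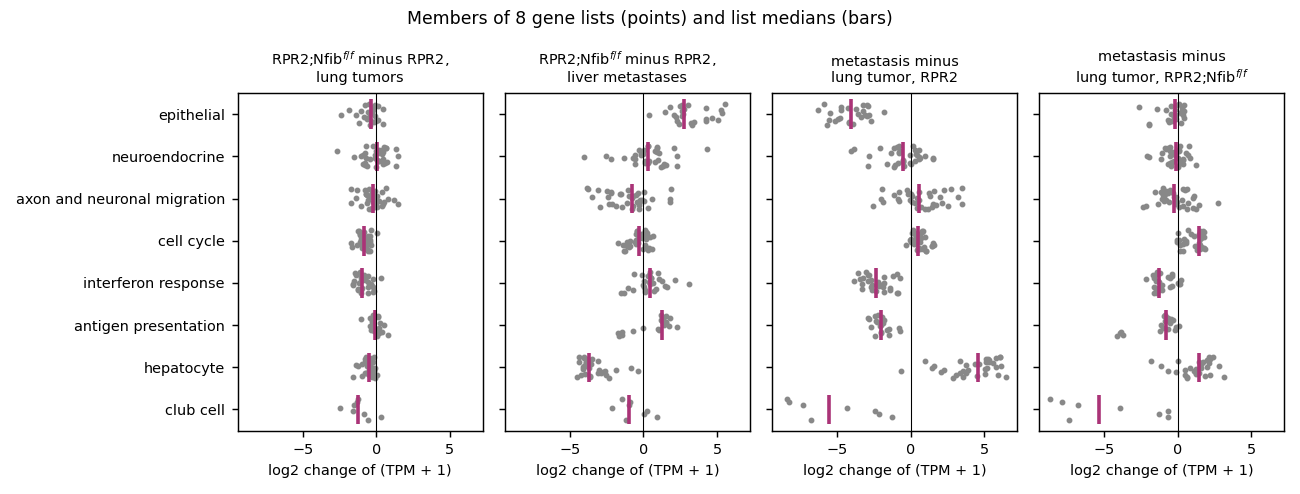
Log2 change of (TPM + 1) of each member of 8 gene lists (grey points) and the list median (bar) in 4 comparisons. Epithelial genes lie at a median of -4.04 in metastases against lung tumors of RPR2 mice and at -0.20 in those of Nfib-floxed mice.

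Over both tissues, with mouse as a random effect, the mean genotype effect was positive for epithelial genes (median 1.36) and negative for some genes of neurons. For epithelial genes this mean joins a median of -0.39 in lung tumors and of 2.73 in liver metastases, so it does not describe both tissues. R3hdml was 3.15 ± 0.24 log2 units higher (adjusted p = 0.00108), Cdh1 2.52 ± 0.24 and Klk1b22, a kallikrein, 3.86 ± 0.66. Neurod4 was lower (-3.68 ± 0.37, adjusted p = 0.00526), as were Kcnj3, a potassium channel gene (-3.13 ± 0.32), and Gap43 (-2.72 ± 0.43). Of the 26 epithelial genes 9 rose (20 adjusted over the list alone, adjusted p = 0.328 with an estimated correlation), and of the 37 axon and neuronal migration genes 2 fell (5 fell and 1 rose adjusted over the list alone, adjusted p = 0.578 with an estimated correlation). The epithelial count of 9 became 2 without either RPR2 metastasis, 5 without the lung tumors of JHK1373, JHK1548 or JHK997, and 15 without the Nfib-floxed metastasis of JHK1398 or with array weights. Ankrd37 and Aldoa rose among 21 hypoxia genes (5 adjusted over the list alone, adjusted p = 0.578 with an estimated correlation). Beside them, hepatocyte markers lay lower (median -2.10, none of 34 passed, 30 fell adjusted over the list alone), as did Kupffer cell (-1.50, none of 8 passed, 7 fell adjusted over the list alone, adjusted p = 0.0201 in fry), neutrophil (-0.98) and macrophage markers (-0.54). Cell cycle (-0.53, 11 of 36 fell adjusted over the list alone) and ribosome biogenesis genes (-0.30) lay lower and antigen presentation (0.50) and mitochondrially encoded genes (0.39) higher, with no member past the threshold. For these 8 lists the adjusted p ranged from 0.328 to 0.866 with an estimated correlation, computed without the mouse effect.

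Other genes higher in Nfib-floxed tumors over both tissues were Piezo2 (2.86), Nrgn (2.85), Ano9 (2.83), Vwf (2.82), Mapk13 (2.82) and Clstn2 (2.69). Lower ones were Mpdz (-3.19), Gng4 (-3.11), Slc6a15 (-3.05), Grik2 (-2.45), Rps6ka6 (-2.41), the actin-bundling protein gene Fscn1 (-2.33), Fndc4 (-2.31) and Dctd (-2.08). In all 65 genes rose and 26 fell, 91 together, and 99 without the mouse effect (estimated correlation between tumors of a mouse 0.051). The count was 28, 43 and 30 without the RPR2 lung tumors of JHK1373, JHK1394 and JHK1548, and 294, 55 and 33 without the Nfib-floxed lung tumors of JHK1398, JHK1399 and JHK997. It was 18 and 19 without the RPR2 metastases of JHK1373 and JHK1394, and 237 and 234 without the Nfib-floxed metastases of JHK1398 and JHK1399. Array weights gave 362 genes, and leaving out the lung tumors of JHK1394 and JHK1398 gave 231. In simulated data 19.7%, 64.1% and 100% of genes changed by 1, 2 and 4 log2 units were recovered.

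On average over both genotypes, metastases had lower lung and immune genes and higher liver and cell cycle genes than lung tumors. The club cell genes Scgb1a1 (-8.52 ± 1.07) and Scgb3a2 (-8.06 ± 0.88) fell, with the surfactant genes Sftpc (-6.42), Sftpd (-5.38), Sftpa1 (-4.91), and with Obp2a (-5.14) and Retnla (-4.67). Of 36 cell cycle genes 12 rose, among them E2f2 (1.52 ± 0.30) and Foxm1 (1.30 ± 0.29), and 23 when adjusted over the list alone (adjusted p = 0.437 with an estimated correlation). Of 20 antigen presentation genes 12 fell, among them Cd74 (-3.26 ± 0.77) and H2-Ab1 (-2.97 ± 0.71), and 17 when adjusted over the list alone (adjusted p = 0.437 with an estimated correlation and 0.0358 in fry). In the Scgb1a1-rich lung tumor of JHK1398, H2-Ab1 was among 4 consecutive genes at least 4-fold above the median of the other libraries (longest of 1000 shuffles 4). Of 29 interferon response genes 12 fell (25 adjusted over the list alone, adjusted p = 0.437 with an estimated correlation and 0.0332 in fry).

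Of 26 epithelial genes 21 fell (26 adjusted over the list alone, adjusted p = 0.298 with an estimated correlation), although the interaction shows that this mean joins unequal effects. Of 34 hepatocyte genes 27 rose (30 adjusted over the list alone, adjusted p = 0.437 with an estimated correlation), with Tm4sf4 (3.77) and Bhmt (4.06) beside them. This rise was not found in every metastasis. The hepatocyte list summed to 620 TPM in the metastasis of JHK1398 and to 1560 TPM in the lung tumor of that mouse. Beside the hepatocyte genes, 5 of 8 club cell, 5 of 11 alveolar type 2, 4 of 10 alveolar type 1, 5 of 9 B and plasma cell, 5 of 9 lung endothelium, 3 of 16 endothelium, 3 of 19 macrophage and 3 of 8 alveolar macrophage genes fell. Adjusted over the list alone, these falls numbered 8, 10, 7 (with 1 rise), 8, 5, 8, 13 and 3 in the same order. Among the lists of tumor programs, 8 of 26 non-neuroendocrine, 2 of 20 NF-kB and 1 of 22 integrin and adhesion genes fell. Some non-neuroendocrine genes were highest in the Scgb1a1-rich lung tumor of JHK1394. Tgfbi had 138 TPM there, and 12.2 and 24.7 TPM in the RPR2 lung tumors of JHK1373 and JHK1548. Lgals3 had 350 TPM there, and 46.7 and 87.2 TPM in these. Not all did so, as Slc16a5 had 5.81 TPM there and 19.4 TPM in JHK1373. Normal lung was thus not separated from a change in the tumor. Adjusted over the list alone, 14, 7 and 10 fell, and 1 integrin and adhesion gene rose. Of 8 Kupffer cell genes 3 rose, with a list median of 0.20, and Gnl3 rose among 26 ribosome biogenesis genes. The lists of mesothelium (-1.43), erythroid (1.23) and oxidative phosphorylation genes (0.14) were called by camera with no member past the threshold. The erythroid list summed to 64959 and 42988 TPM in the metastases of JHK1373 and JHK1399, but to 4142 and 476 TPM in those of JHK1394 and JHK1398. Over the 21 lists called, the adjusted p ranged from 0.298 to 0.583 with an estimated correlation.

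The comparison of metastasis against lung tumor over both genotypes gave 911 changed genes, 273 higher and 638 lower in metastases. With quantile normalization the split was 371 and 381, with median centring 342 and 384, and the median log2 change of all genes was -0.10. With mouse as a fixed block the count was 358, with a pseudocount of 5 it was 579 and without the filter 513. It was 526 without the RPR2 lung tumor of JHK1394, 580 without the Nfib-floxed lung tumor of JHK997, 254 and 217 without the RPR2 metastases of JHK1373 and JHK1394, and 383 without the Nfib-floxed metastasis of JHK1398. Without the lung tumors of JHK1394 and JHK1398 it was 495. In simulated data 12.1%, 60.3% and 97.7% of genes changed by 1, 2 and 4 log2 units were recovered.

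Effects were compared across genes between comparisons that share no library. The genotype effect in lung tumors correlated with that in metastases at r = 0.132 (Spearman 0.167) over 15503 genes, and the tissue effect in RPR2 mice with that in Nfib-floxed mice at r = 0.396 (Spearman 0.329). Genes are not independent replicates, so no p is given, and the lung tumors and metastases of the first pair come partly from the same mice. Of the 19 genes that fell in Nfib-floxed metastases, 12 also fell in RPR2 metastases, against 0.678 for independent lists.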

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

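The test of dilution by liver cells was chosen after its result was seen. That of scaling was set before its own result, but after the 18 epithelial genes called in the liver comparison were known. The genotype effect differed between lung tumors and liver metastases for 90 genes in the interaction test of limma, and the genes and lists given here were singled out by that test. Positive differences, with a higher genotype effect in metastases, were those of Tspan1 (6.40), Cdh1 (5.99), R3hdml (5.78), Esrp1 (5.68), Aldh1a3 (5.67), Mapk13 (5.62), Ret (5.6), Ano9 (5.54), Cldn7 (5.53), Ehf (5.27), Ap1m2 (5.23), Enpep (5.23) and Ankrd37 (2.75). Negative differences were those of Adamts10 (-5.31), Tceal3 (-4.97), Lingo1 (-4.89), Grik2 (-4.51), Slc6a15 (-4.19), the actin-binding protein gene Dbn1 (-4.08), Rps6ka6 (-4.03), Fndc4 (-3.91), Adgrl3 (-3.81), Cyp2a4 (-3.59), Plppr5 (-3.55) and Epha5 (-3.45).

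By camera, 13 lists had a genotype effect that differed between tissues, none of them with an estimated correlation. Median log2 differences were positive for epithelial genes (3.5), hypoxia and glycolysis (1.58), interferon response (1.30), antigen presentation (1.35) and cell cycle genes (0.56). They were negative for hepatocyte (-3.02), fibroblast stroma (-0.81), Kupffer cell (-1.36), axon and neuronal migration (-0.34), B and plasma cell (-2.0), neutrophil (-1.21), mitochondrially encoded (-0.58) and liver sinusoidal endothelium genes (-0.84).

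Epithelial genes were low in both RPR2 metastases, which also held more hepatocyte RNA than the Nfib-floxed ones. Dilution of tumor RNA by liver cells would lower all tumor genes alike, but in RPR2 metastases the epithelial median (-4.04, 26 genes) lay -3.52 log2 units from the neuroendocrine median (-0.53, 35 genes). That difference gave a permutation p of 1e-05 across genes, the smallest that 100000 permutations can give, and genes are not independent replicates. Scaling of TPM by a few abundant transcripts was also argued against, since at least 16 epithelial genes passed in the liver comparison after quantile normalization and after rescaling without the cell type lists. What stays open is whether the genotype or another difference between the 2 mice of each genotype lies behind the pattern. Open too is whether the metastasis of JHK1398, which correlated most with the RPR2 lung tumor of JHK1373 (0.932), has the right label. It also shared raised genes on chromosome 4 with tumors of JHK1373, as given below. Runs that hold Srm had medians of 1.86 in this metastasis and 1.425 in the RPR2 lung tumor of JHK1373. The 4 genes around Mycl were raised in this metastasis and in the metastasis of JHK1373. Without the metastasis of JHK1398 the epithelial median in the liver comparison was 3.41, but that fit does not use the library and cannot test its label.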

How the results depend on the processing

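The alternative without the lung tumors of JHK1394 and JHK1398 was chosen after seeing the data, and the others before. Changed genes in lung tumors numbered 1 with a pseudocount of 0.1. In liver metastases they numbered 193 with a mean TPM of at least 5 and 0 with only the 2 groups compared. For metastasis against lung tumor in RPR2 mice, array weights gave 2069. In Nfib-floxed mice, the 19 became 40 and 1 with pseudocounts of 0.1 and 5, 2 without the filter, 9 with median centring, 0 with only the 2 groups compared and 1 without the 2 lung tumors. The interaction count was 142 with array weights and 24 without the 2 lung tumors. The genotype effect over both tissues gave 362 with array weights and 231 without the 2 lung tumors. The tissue effect over both genotypes gave 579 with a pseudocount of 5, 513 without the filter and 495 without the 2 lung tumors. Fewer samples enter the fits of 2 groups and those without the 2 lung tumors, and the cause was not tested for the others.

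With mouse as a fixed replicate block, which uses only the pairs, the count was 530 for metastasis against lung tumor in RPR2 mice, 13 for the interaction and 358 over both genotypes. The block, fixed or random, moved no other count of genes by over 1.5 times, while the fixed block ended 54 calls of named genes. With an estimated correlation 0 lists were called in each comparison. Fry called 0 in lung tumors, 2 in metastases, 5 between tissues in RPR2, 0 in Nfib-floxed mice, 1 for the interaction, 2 for genotype and 8 for tissue over both.

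Leaving out each library in turn gave 0 to 1 genes in lung tumors, 110 to 338 in metastases, 243 to 646 between tissues in RPR2 mice and 0 to 29 in Nfib-floxed mice. It gave 24 to 124 for the interaction, 18 to 294 for genotype over both tissues and 217 to 871 for metastasis against lung tumor over both genotypes. Where this left 1 sample in a group, that sample was assumed to vary like the other groups. The log2 change of Nfib between tissues in RPR2 mice ran from -0.069 without the metastasis of JHK1394, a reversal from 1.60, to 3.27 without that of JHK1373. For Nfib: interaction of genotype and tissue, the value ran from -2.91 without JHK1373 to 0.42 without JHK1394, a reversal from -1.24. The 643 TPM of Nfib in the metastasis of JHK1394 show the cause. Of the other named genes' results, no direction reversed. Without either RPR2 metastasis, however, more of them were no longer past the threshold than stayed past it. Without the filter, 97 were no longer past it and 140 were unchanged. The agreement of tissue effects was 0.396 and became 0.36 without the cell type lists. No list called by camera changed direction under quantile normalization, median centring or rescaling. The depth is unknown, so its part in these limits cannot be given.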

Other observations

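The genes of the first 3 paragraphs and the tests of hepatocyte RNA beside Nfib, of hepatocyte RNA in the 4 genes around Mycl and of a narrower Mycl segment were chosen after the values were seen. In Nfib-floxed against RPR2 metastases, Syt5 (3.22 ± 0.69), the syntaxin gene Stx1a (3.32 ± 0.68) and the vesicular monoamine transporter gene Slc18a1 (3.81 ± 0.65) rose and Grik2 fell, 4 of the 32 synaptic genes (3 up and 2 down adjusted over the list alone), while 0 of the 35 neuroendocrine genes passed (2 fell adjusted over the list alone). In RPR2 metastases against lung tumors, Syt5 (-3.16 ± 0.63) and Slc18a1 (-4.07 ± 0.59) fell and Grik2 rose (4.45 ± 0.40). Of 35 neuroendocrine genes, 3 fell in RPR2 metastases, namely Resp18 (-2.82 ± 0.58), Celf3 (-1.60 ± 0.38) and the prohormone convertase gene Pcsk1 (-2.92 ± 0.69), and 3 adjusted over the list alone. Of 24 mesenchymal genes, Zeb1 (1.94 ± 0.50) and Snai2 (2.0 ± 0.50), which encode repressors of E-cadherin, rose in RPR2 metastases, while Tgfb3 (-1.67 ± 0.36) and Thbs1 (-4.16 ± 0.91) fell. Snai2 had 9.9 ± 0.129 TPM in RPR2 and 0.632 ± 0.178 TPM in Nfib-floxed metastases. Calca, which encodes calcitonin and its related peptide, took 0.0545% and 0.141% of TPM in the RPR2 metastases of JHK1373 and JHK1394, 0.547% and 5.75% in the Nfib-floxed metastases of JHK1398 and JHK1399, 0.604%, 6.85% and 7.19% in the Nfib-floxed lung tumors of JHK1398, JHK1399 and JHK997, and 0.916% to 1.82% in the RPR2 lung tumors.

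Camera called none of the lists for cilia, T and NK cells, dendritic, hepatic stellate, bile duct, tuft, basal, nerve and muscle cells, or for the neuroendocrine, synaptic, Notch, Wnt, foregut, immediate early and sex-linked genes, in any comparison. Y-linked Ddx3y was at 28.5 TPM in the lung tumor and 5.10 TPM in the metastasis of JHK1394, at 64.9 TPM in the lung tumor of JHK997 and under 1 TPM in the other libraries. Genes on chromosome X had a median log2 difference of 0.90 to the other libraries in the lung tumor of JHK1399, and those on chromosome 19 one of -0.66 in its metastasis. From both values the library's median over all chromosomes was subtracted, which was not done for the runs and neighbors below. In the metastasis of JHK1398, 2 adjoining runs of 11 protein-coding genes on chromosome 4 (148004259 to 149166771) had median log2 differences of 1.379 and 1.86 to the other libraries (highest of 100 shuffles 0.776), and a run that holds Mycl (120968317 to 123132099) one of 0.964. In the RPR2 lung tumor of JHK1373, runs from 148160621 to 148954889 and from 149328416 to 150009023 had medians of 1.425 and 1.684 (highest of 100 shuffles 1.094).

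In the metastases of JHK1398 and JHK1373, 4 genes on chromosome 4, consecutive among protein-coding genes with a mean of at least 5 TPM (122836242 to 123054949, GRCm38), Ppt1, Cap1, Mycl and Trit1, each stood at least 4-fold above the median of the other libraries, longer than the longest runs of 2 and 3 in 1000 shuffles of gene order, with Mycl at 981 and 482 TPM. In JHK1398, 2 further stretches of 3 such genes on chromosome 4 also exceeded the shuffles, Slc2a1, Zfp691 and Svbp (119108711 to 119201298, median log2 difference 5.06) and Srm, Tardbp and Gm572 (2.10), which lie inside the longer runs given above, and in JHK1373 Ppie (2551 TPM), Pabpc4 (2388 TPM), Ndufs5 (6471 TPM) and Akirin1 (656 TPM) were raised too, up to position 123750345. A gain reaching far toward higher positions was argued against in JHK1398, where 20 neighbors within 1 Mb had a median log2 difference of -0.02 (0.68 in JHK1373). Most of these neighbors lie at higher positions than Mycl. The test therefore cannot decide on a wider gain toward lower positions, where the stretch with Slc2a1 lies. There, the run from 120968317 to 123132099 had a median of 0.964 (highest of 100 shuffles 0.776). A candidate explanation for the 4 genes in JHK1398 is a narrower gain, which leaves the longer runs near Srm unexplained. In the metastasis of JHK1394, 7 neighbors of Nfib within 1 Mb had a median of 1.57, so a gain carrying Nfib may lie behind its 643 TPM, and hepatocyte RNA was argued against by their level 1.66 above that in the hepatocyte-rich metastasis of JHK1373. For the 4 genes around Mycl, hepatocyte RNA was argued against by a median log2 level at least 3.85 above that in the hepatocyte-rich metastasis of JHK1394 in both metastases, while a test over all neighbors of Mycl (-0.93) decides nothing because they were not raised as a set in JHK1398, and since clusters of cell type genes also form such stretches and no DNA data were used here, gains stay hypotheses.

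Cell cycle genes had a median log2 difference of -0.80 between Nfib-floxed and RPR2 lung tumors. A larger share of normal lung in the tumor of JHK1398 was argued against, since without it and the lung tumor of JHK1394 the median was -0.79. The list was not called with an estimated correlation (adjusted p = 0.996), and whether the genotype or another difference between the mice lies behind the pattern stays open.

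Other splits of the samples were counted as planned. The lung comparison had 0 genes, so all 10 splits of the 6 tumors had to give as many, and this count decides nothing. The highest other gave 2, and 10 splits are in any case too few for a share under 0.05. For genotype over both tissues, 1 of 6 splits of the mice, the real one with 91 genes, was that large and the highest other gave 34, again too few splits. For tissue over both genotypes, 1 of 100 splits, the real one with 911 genes, was that large and the highest other gave 776. Of the 16 that part all 4 pairs, as the real one does, 1, the real one, was that large and the highest other gave 293, but 16 splits are too few for a share under 0.05. The split with 776 keeps both RPR2 metastases in place and leaves the 2 tumors of JHK1398 together. Every split with both RPR2 metastases in the metastasis group gave at least 74 genes, and every other split gave at most 2. The count thus rests largely on the 2 RPR2 metastases, and the splits cannot show a tissue effect in both genotypes.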
